A study of Arabidopsis thaliana with 20 samples.

How the data were processed

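RNA of Arabidopsis thaliana was measured on 20 Affymetrix arrays of 22810 probe sets each. Per the labels' protocols, plants grew at 22 °C under constant light on half-strength Murashige and Skoog agar that held 2% sucrose, RNA was purified on RNeasy columns, and biotin-labelled cRNA was made from 10 micrograms of total RNA. The deposited values are linear intensity values, 1 signal per probe set and array; per the submitters' processing notes they were made with MAS5, whose version is not given in the sources used here. On every array the mean signal after trimming 2% of probe sets at each end was 500.04 to 500.06, so the authors had scaled each array to the same level. How many plants went into a sample and where the replicates came from is not given in the sources used here, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value: 3 or 2 per leaf group, and 1 per seedling genotype.

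From these signals each array was scaled to the same trimmed mean, values under a floor of 33.1 were set to it, and log2 was taken. The floor was the median over the 20 arrays of each array's 25th percentile. In leaves, a probe set was tested if it lay above the floor on every array of at least 1 group, which left 16558 probe sets, 9149 of them named. The 10 leaf arrays were fitted together with a mean per group in limma 3.58.1 under R 4.3.3, with a variance trend on the mean, 6 residual degrees of freedom and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was taken as a call. The comparisons were triple mutant minus wild type at 5 d and at 15 d, the difference between those effects, and 15 d minus 5 d in each genotype. All tests were two-sided. In seedlings, 19626 probe sets above the floor on at least 1 array were used. With 1 array per genotype a single seedling genotype had no test: its log2 ratio over wild type was given, and a list's median ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins. A second limma fit over the 10 seedling arrays had 1 additive term for each of the 4 mutant alleles and 5 residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

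Probe sets were named from the gene table supplied with the data, whose assembly is TAIR10.1 and which was used for names and neighbours only. Of the 22810 probe sets, 13513 paired with 1 gene, 503 with several and 8730 with no name, and 64 were array controls; 13436 matched the table. Of 268 genes on the planned lists only 33 had a named probe set, so most well-known cell-cycle genes are not analysed here. The lists fixed before the data were examined numbered 20: the MYB3R family, G2/M genes, G1/S and DNA replication genes, D-type cyclins, cyclin-dependent kinase inhibitors and endocycle genes, DNA damage response, photosynthesis, ribosome and nucleolus, leaf growth regulators, senescence, salicylic acid and defence, jasmonate and wounding, cold, drought and abscisic acid, heat shock, circadian clock, stomatal lineage, trichome, shoot meristem and boundary, root, and flower genes. Because so few members had a named probe set, 12 lists taken by name from the gene table were added after the coverage was seen: kinesin, chromosome segregation, DNA replication, core histone, cytosolic ribosomal protein, nuclear photosynthesis, expansin and xyloglucan endotransglucosylase/hydrolase (XTH), UDP-glycosyltransferase, glutathione S-transferase, tubulin, plastid-encoded and mitochondrion-encoded genes. Lists with at least 5 tested members were compared with the other probe sets by camera with its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation.

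The groups, the tests, the 20 lists and the rule for named genes were fixed before the data were examined. The rule took, per leaf comparison, the 8 largest rises and the 8 largest falls among calls with exactly 1 gene, a higher group mean of at least 4 times the floor and arrays of both groups that did not overlap (for the difference of effects, calls alone); chance gives such non-overlap in 10% of 3 against 3 and 33.3% of 2 against 2 comparisons. Per list it took the 2 largest called rises and the 2 largest called falls, or the 2 members with the highest mean signal where none was called. In seedlings it took the 4 largest ratios each way in the triple, the myb3r1 myb3r4 and the quadruple mutant; of probe sets without a gene name, at most 2 that rose and 2 that fell are printed. Genes named outside the rule are marked as chosen after their values were seen. Where a group lay at the floor on every array, or on 2 of 3, the fold or log2 change is given as at least that value.

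Whether the replicate numbers pair the samples was checked from the correlation of their deviations from the group means. At 15 d the samples with the same number correlated at 0.73, 0.60 and 0.57, all over the limit of 0.1. Samples with different numbers correlated at -0.67 to 0.42. Mutant replicate 2 with wild-type replicate 3 (0.42) and mutant replicate 3 with wild-type replicate 2 (0.15) passed the limit too. Each mutant sample correlated highest with the wild-type sample of its number, so the numbers were treated as a possible pairing. With 3 samples per group this does not establish it, and the labels do not explain the numbers. At 5 d there were only 2 pairs, with a correlation of 0.48, and across ages the same number correlated at -0.25 to 0.19. A fit with the replicate number as a block within each age, with 3 residual degrees of freedom, was therefore added after the data were seen. The other alternatives were the values as deposited, quantile normalization, no floor, a pseudocount equal to the floor in place of it, and no filter. Also used were a filter at 2 times the floor, no variance trend, a replicate block across ages, an ordinary linear model, and only the groups of the comparison. The last left out each array in turn or, added later, both 15 d arrays of one number. For the allele terms the quantile normalization, floor, pseudocount, filter, variance trend and leave-one-out alternatives were used too, with a myb3r1 by myb3r4 interaction and with myb3r3 and myb3r5 as 1 term.

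The fits were tested on simulated data with the real means and spreads. At 15 d the fit recovered 9.30% of 86 probe sets changed 2-fold and 59.6% of 114 changed 4-fold; at 5 d it recovered 1.87% of 107 and 33.3% of 93. The myb3r4 term recovered 86.7% of 98 and 97.1% of 102. With the G2/M list moved by known changes, camera called it in 20 of 20 draws. Of the lists left in place, the core histone and the nuclear photosynthesis list were each called in 1 of 20. The simulated noise was drawn independently for each probe set and array, without correlation between genes or pairing of samples. How often lists of correlated genes are called wrongly was therefore not measured. Array checks found 21.4 to 24.6% of probe sets at the floor in seedlings and 25.8 to 35.1% in leaves, control 3′ over 5′ ratios in seedlings and leaves of 1.71 to 2.69 and 0.907 to 1.85 for GAPDH, 7.97 to 22.4 and 10.97 to 25.98 for actin, and 2.93 to 4.72 and 2.22 to 3.22 for ubiquitin, correlations of 0.912 to 0.983 between replicates, and no duplicated array. Promoter motifs were not analysed here, because no genome sequence was used.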

Results

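Gene expression was measured in 2 tissues of Arabidopsis plants carrying mutations in MYB3R genes, which encode MYB transcription factors known to act on the promoters of genes expressed at the G2/M transition. First leaf pairs came from wild type and from the myb3r1 myb3r3 myb3r5 triple mutant, with 2 arrays per genotype at 5 d and 3 per genotype at 15 d. Seedlings of 9 d came from wild type and 9 mutant genotypes with 1 array each: the 4 single mutants, the myb3r1 myb3r4 and myb3r3 myb3r5 double mutants, the myb3r1 myb3r3 myb3r5 and myb3r3 myb3r4 myb3r5 triple mutants, and the quadruple mutant. The small number of arrays limits the precision throughout. None of the 5 MYB3R genes had a named probe set, so the loss of the targeted transcripts was not checked and genotypes are as labelled.

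In 15 d leaves, where most cells have left the cell cycle, genes of mitosis and cytokinesis were higher in the triple mutant than in wild type. AUR2, which encodes a mitotic Aurora kinase, rose at least 19.4-fold, from a mean signal of 22.9 ± 15.5 (SD, n = 3) in wild type to 690.3 ± 80.0 (SD, n = 3) in the mutant (log2 change 4.28, SE 0.18, adjusted p = 2.3e-05), with 2 of the 3 wild-type arrays at the floor of 33.1 against which folds are taken. The related kinase gene AUR1 rose 9.80-fold, from 60.4 ± 39.7 to 543 ± 60.1 (log2 change 3.29, SE 0.38, adjusted p = 0.0040). KINESIN-12B, a kinesin of the phragmoplast, rose 7.01-fold, from 39.2 ± 12.2 to 291 ± 23.6 (log2 change 2.81, SE 0.22, adjusted p = 2.9e-04). For both genes 1 of 3 wild-type arrays was at the floor. BUBR1 of the spindle checkpoint (at least 2.71 on the log2 scale, adjusted p = 0.0037; wild type at the floor) and 3xHMG-box1, which encodes a protein that binds mitotic chromosomes (at least 3.08, adjusted p = 0.012; 2 of 3 wild-type arrays at the floor), also rose. Both were chosen for naming after their values were seen. Of 8 tested G2/M genes these 5 rose and none fell, and 6 rose when adjusted over the list alone, the sixth being 3xHMG-box2 (adjusted p = 0.040 over the list, 0.50 over all probe sets; 129 ± 91.3 in the mutant). AUR3 (-0.17) and AT1G63100 (0.12) did not pass either test. The median change of the list was 2.76, it was up by camera (adjusted p = 6.7e-13, and 0.013 with an estimated correlation), and it was 2.30, 3.05 and 2.84 in the 3 pairs of samples with the same number.

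**Figure D1:**
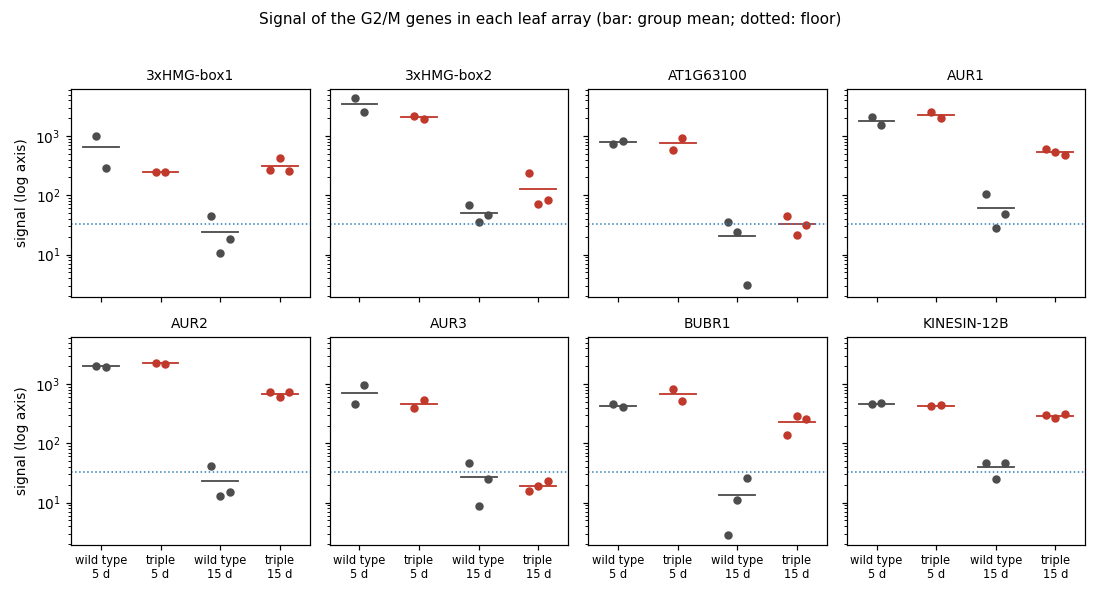
Signal of the 8 tested G2/M genes on each of the 10 leaf arrays (log axis), by genotype and age; bars are group means and the dotted line is the floor of 33.1. AUR2 stood at a mean of 22.9 in 15 d wild type and 690.3 in the 15 d triple mutant.

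Across all 16558 probe sets, limma called 124 at 15 d, 120 higher and 4 lower in the triple mutant (1461 at an unadjusted p under 0.05), of which 70 higher and 2 lower had a gene name. With folds taken against the floor, the largest named change was AT4G01730, at least 30.0-fold higher (log2 change 4.90, SE 0.20, adjusted p = 2.3e-05). Its signal was 18.6 ± 6.46 in wild type, under the floor, and 1003 ± 182 in the mutant. AT3G27330, AT5G48310, AT4G14490, AT1G23790 and AT2G16270 were at least 15.0, 13.4, 12.1, 11.4 and 9.97-fold higher, with wild-type means of 7.58 to 24.3 that lay under the floor, and AT4G28230 was 12.0-fold higher (adjusted p = 0.0012). The falls were small: AT2G01870 fell by 1.35 (adjusted p = 0.037; 547 ± 34.4 against 220.4 ± 61.6) and AT1G28570 by 1.28 (adjusted p = 0.033; 461 ± 70.1 against 189 ± 23.1) on the log2 scale. Both falls lost their call without any array but 15 d mutant replicate 1, with adjusted p = 0.089 to 0.19 and 0.071 to 0.18. AUR1 lost it only without both 15 d arrays numbered 2 (adjusted p = 0.072) or numbered 3 (0.10). The count was 72 and 75 without 15 d wild-type replicate 2 and 3, and 43 and 58 without both 15 d arrays numbered 2 and 3. It was 1414 (635 higher, 779 lower) without 15 d mutant replicate 1, 1552 without both arrays numbered 1, and 779 (409 higher, 370 lower) with the samples paired by number within each age; each of these included all 124. With only the 15 d arrays fitted it was 67.

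Beyond the G2/M list, 6 of 28 tested kinesin genes rose at 15 d, and 8 did when adjusted over the list alone. AT1G72250 was at least 8.54-fold higher (log2 change 3.09, SE 0.29, adjusted p = 9.1e-04), and KINESIN-12B is on this list too. The others, chosen after their values were seen, were AT2G37420 (at least 2.60), AT4G14330 (at least 2.53), AT3G44050 (at least 2.45) and AT2G22610 (adjusted p = 0.019). Wild type was at the floor in 3 of 3 arrays for AT4G14330 and AT3G44050 and in 2 of 3 for the others. The list was up (adjusted p = 1.7e-04; adjusted p = 0.38 with an estimated correlation), with a median of 0.00 and a mean of 0.55. Of 12 chromosome segregation genes AT5G15510 rose at least 6.66-fold (2.74, SE 0.20, adjusted p = 1.8e-04); adjusted over the list alone the checkpoint genes BUB3.1 (0.79) and BUB3.2 rose and AT3G48210 (-0.91) fell as well, each chosen after its value was seen. That list was up with a median of 0.11 (adjusted p = 0.021; adjusted p = 0.35 with an estimated correlation), but not without wild-type replicate 3 (adjusted p = 0.064), without mutant replicate 1 (0.085) or with the pairing (0.071). Of 7 tubulin genes TUB7, a beta-tubulin gene, rose 2.85-fold (1.51, SE 0.22, adjusted p = 0.015; 354 ± 105 against 984 ± 109), as it did over the list alone. Its call was lost without either 5 d replicate 1, or without 15 d replicate 2 or 3 of either genotype (adjusted p = 0.052 to 0.081). The tubulin list was up with a median of 0.41 (adjusted p = 0.033; adjusted p = 0.35 with an estimated correlation). It missed the threshold without wild-type replicate 2 (adjusted p = 0.067), mutant replicate 1 (0.28) or 3 (0.058), both arrays numbered 1 (0.31), and with the pairing (0.069).

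Nuclear genes of photosynthesis stood lower as a group in the 15 d triple mutant, while none of their 11 tested members was called. The list's median change was -1.42 (camera adjusted p = 1.8e-06; adjusted p = 0.35 with an estimated correlation), and all 11 members were lower in each of the 3 pairs, whose medians were -0.38, -2.51 and -1.63. RCA, the Rubisco activase gene, had signals of 15069.6 ± 6861 in wild type and 8095 ± 9134 in the mutant (log2 change -1.41, SE 0.69, adjusted p = 0.61). LHCB4.1, of the light-harvesting antenna, had 14807 ± 5791 and 7837 ± 7436 (-1.26, adjusted p = 0.57). These genes were called without 15 d mutant replicate 1, with adjusted p = 0.0080 and 0.0071. LHCB4.3 (-1.78), chosen after its value was seen, was the 1 gene lower when adjusted over the list alone. Senescence genes were too few for a list test, and none was called: 4 were measured, all with positive changes and a median of 0.63, SAG29 at 1.17 and WRKY53 at 0.24.

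**Figure D2:**
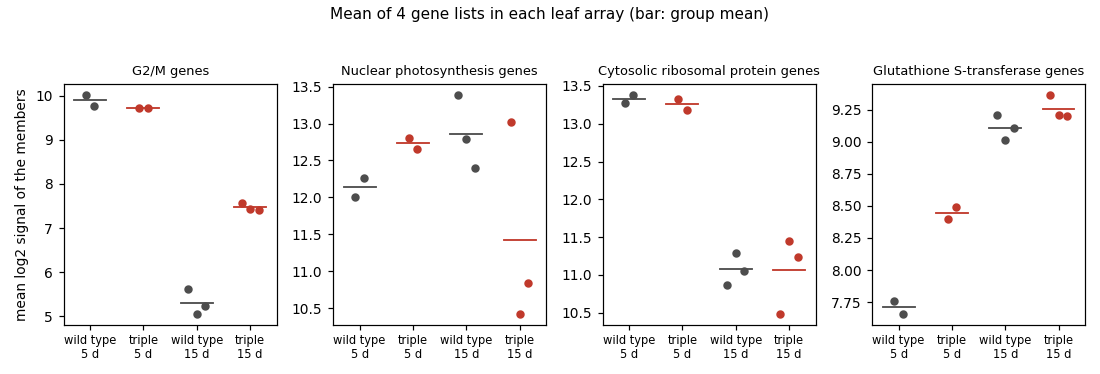
Mean log2 signal of the G2/M, nuclear photosynthesis, cytosolic ribosomal protein and glutathione S-transferase lists on each leaf array, by genotype and age. In the 15 d triple mutant the G2/M median was 2.76 higher and the photosynthesis median 1.42 lower than in wild type on the log2 scale.

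Ribosomal, replication and histone genes showed no call at 15 d. The 45 cytosolic ribosomal protein genes had a median of -0.04 (adjusted p = 0.79), but the list was up without mutant replicate 1 (adjusted p = 0.0013) or both arrays numbered 1 (0.015), and down without mutant replicate 2 (0.00053). DNA replication genes (7 tested; median -0.10, adjusted p = 0.46), core histone genes (8; 0.05, 0.44), expansin and XTH genes (18; 0.17, 0.39) and UDP-glycosyltransferase genes (36; median 0.04, mean -0.10, down by the test, 0.46) had no called member. UGT88A1, a UDP-glycosyltransferase gene (-1.41, adjusted p = 0.34), was called without mutant replicate 1 (adjusted p = 0.0093) and with the pairing (0.015). Glutathione S-transferase genes (8; median -0.08, mean 0.15, down by the test, adjusted p = 0.97) had none called, and GSTU25 (at least 2.04, 2 of 3 wild-type arrays at the floor) and GSTU27 (-0.62), chosen after their values were seen, passed when adjusted over the list alone. The 47 plastid-encoded genes had a median of 0.11 (adjusted p = 0.70). They were up without wild-type replicate 1 (adjusted p = 0.017), mutant replicate 2 (0.0012) or both arrays numbered 2 (0.015), and down without both numbered 3 (0.042). The 12 mitochondrion-encoded genes were not called (median 0.43, adjusted p = 0.066). They were up with the pairing (adjusted p = 0.0115), with a replicate block across ages (0.039), without 15 d wild-type replicate 3 (0.021), 15 d mutant replicate 2 (0.0064), 5 d mutant replicate 1 (0.031) or 2 (0.037), or both 15 d arrays numbered 2 (0.045). Among small lists, with values only, the replication genes PRL (-0.42) and ICU2 (-0.34), the cell-cycle inhibitor gene SIM (-0.16), the leaf shape gene AN (-0.09), the clock gene GI (-0.13), the trichome gene TRY (-0.15), the stomatal gene FMA (-0.10), the defensin gene PDF1.2 (-0.83) and the ribosomal genes AT2G19730 (-0.20) and AT3G09630 (-0.12) were not called. The cold-regulated gene COR47 (1.07, adjusted p = 0.41) was called with the pairing (adjusted p = 0.028). The root gene EXPA18 was at the floor in both genotypes. Lists of D-type cyclins and of DNA damage, salicylic acid, heat shock, meristem and flower genes had no tested member.

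In 5 d leaves, which still proliferate, the G2/M genes were not called: the median of the 8 genes was -0.10 (camera adjusted p = 0.52), and AUR1 had signals of 1803 ± 386 (SD, n = 2) in wild type and 2305 ± 374 (SD, n = 2) in the triple mutant. Among the genes that rose was MSRB5, which encodes a methionine sulfoxide reductase, from 64.9 ± 30.2 to 703 ± 359 (log2 change 3.42, SE 0.39, adjusted p = 0.020). AT1G65490 rose 8.42-fold (3.07, SE 0.28, adjusted p = 0.0062), AT4G03610 6.88-fold (2.78, adjusted p = 0.0055) and AT1G13650 at least 6.37-fold (2.67, adjusted p = 0.0018). AT3G01015 (1.81), AT1G07450 (1.60), AT3G11000 (1.59) and the beta-expansin gene EXPB1 (1.30, at least 2.47-fold) rose with adjusted p = 0.030 to 0.040. The cold-regulated gene COR27 fell by 2.62 on the log2 scale (SE 0.32, adjusted p = 0.029; 221 ± 10.8 against 35.0 ± 5.96, with 1 of 2 mutant arrays at the floor) and AT1G56300 by 2.14 (SE 0.24, adjusted p = 0.020). The unnamed probe set 256099_at fell by 2.07 (adjusted p = 0.031). That call was lost without 15 d wild-type replicate 2 or 3 or 15 d mutant replicate 3, and with a replicate block across ages. The largest rise was that of the unnamed probe set 264823_at (4.74, adjusted p = 0.0021). Of these, AT1G13650 kept its call without each array; AT4G03610 lost it without mutant replicate 2 (adjusted p = 0.056), and AT1G65490 without either replicate 2 (0.070 and 0.095). MSRB5 lost it without any array numbered 2 or a 15 d array numbered 3 (0.050 to 0.13), and with the pairing (0.051). AT1G56300 lost it without the same arrays except 15 d mutant replicate 2 (0.050 to 0.087). AT3G01015, AT1G07450, AT3G11000 and EXPB1 lost it without those 6 arrays or 15 d wild-type replicate 1 (0.057 to 0.14), and COR27 without the 6 or wild-type replicate 1 (0.050 to 0.17).

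At 5 d, limma called 21 probe sets, 18 higher and 3 lower in the triple mutant (859 at an unadjusted p under 0.05); under quantile normalization the split was 23 higher and 11 lower. The count was 52 (44 higher, 8 lower) with samples of the same number paired within each age, 1 with only the 5 d arrays fitted, 111 (47 higher, 64 lower) without wild-type replicate 1, 72 (37 higher, 35 lower) with an ordinary linear model and 523 (464 higher, 59 lower) without mutant replicate 1. It was 4 without mutant replicate 2, 6 without wild-type replicate 2, 6 without 15 d wild-type replicate 2 or 3, 34, 9 and 8 without 15 d mutant replicate 1, 2 and 3. Leaving out 1 of the 2 arrays of a group assumes that the other varies like the remaining groups. Of the 18 rises, 9 (50%) were also higher and 4 (22.2%) lower at 15 d than at 5 d in wild type, against 24.9% and 27.3% of all tested, and 5 were not called with age. The comparisons share the 5 d wild-type arrays, and simulated data without mutant effects gave a share of 58.9% higher on average and 72.2% at most. With a different 5 d wild-type array in each comparison, a test chosen after seeing the data, 6 of 11 rises (54.5%) were higher with age with replicate 2 in the mutant comparison and 0 of 1 with replicate 1, against 18.9% of all tested in both. Mutant replicate 2 stood apart from the other 5 d arrays in genes that rise with leaf age. This covered 1104 other probe sets that rose by more than 3 log2 units from 5 d to 15 d in wild type. Its median was 1.15 (SD 1.04) above the wild-type mean, against 0 (SD 0.593) in mutant replicate 1. The median was 0 on both wild-type arrays too. A median of exactly 0 is what probe sets at the floor give, so it does not show levels equal to wild type.

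**Figure D3:**
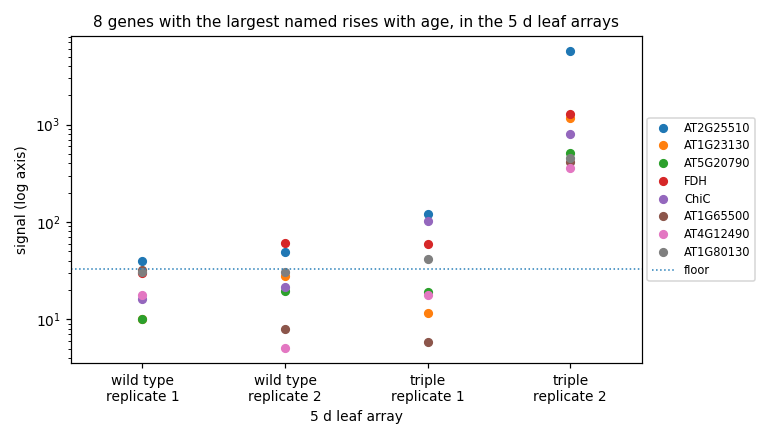
Signal (log axis) of 8 genes that rose strongly from 5 d to 15 d in wild type, on the 4 arrays of 5 d leaves; the dotted line is the floor of 33.1. AT2G25510 had a signal of 5719 in triple mutant replicate 2 and 120.0 in replicate 1.

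Glutathione S-transferase genes, which encode detoxifying enzymes, were higher as a group at 5 d. Their median change over 8 tested genes was 0.75 (camera adjusted p = 8.2e-06, and 0.027 with an estimated correlation), and 0.63 and 0.85 in the pairs of samples with the same number. The list also rises with leaf age in wild type, and mutant replicate 2 stands apart in such genes. Its mean log2 signal was 8.40 and 8.49 in mutant replicates 1 and 2, against 7.76 and 7.66 in wild type, and the list was still higher without mutant replicate 2 (median 0.72, adjusted p = 3.9e-05). None was called over all probe sets, and GSTU20 (0.99; 1813 ± 116 against 3623 ± 448), GSTL3 (0.98; 665 ± 12.3 against 1309 ± 42.5) and GSTU16 (1.44, chosen after its value was seen) rose when adjusted over the list alone. Chromosome segregation genes were lower as a group (12 tested, median -0.37, adjusted p = 7.0e-04; adjusted p = 0.24 with an estimated correlation), with WYR (-0.94, chosen after its value was seen) lower over the list alone. The group was not called without wild-type replicate 1 (adjusted p = 0.084) or without the floor (0.11). Kinesin genes were lower (28 tested, median -0.21, adjusted p = 0.023; adjusted p = 0.81 with an estimated correlation), but not without wild-type replicate 1 (0.94), mutant replicate 2 (0.58) or the floor (0.16). Nuclear photosynthesis genes were higher (11 tested, median 0.65, adjusted p = 0.023; adjusted p = 0.81 with an estimated correlation), but not without replicate 1 of wild type (0.23) or of the mutant (0.47), or without the floor (0.080). None of the kinesin or photosynthesis genes was called. Expansin and XTH genes were not called as a group (median 0.21, adjusted p = 0.097), with EXPB1 the 1 call of 18. The group was up without wild-type replicate 1 (0.024) and under the stricter filter (0.031). Core histone (median 0.11, adjusted p = 0.47; 0.017 without wild-type replicate 1), ribosomal (-0.09, 0.32; 0.044 without mutant replicate 1) and plastid-encoded genes (0.25, 0.28; 0.00015 without wild-type replicate 2 and 0.025 without mutant replicate 1) were not called. Neither were UDP-glycosyltransferase (0.01, 0.28), tubulin (-0.18, 0.47), mitochondrion-encoded (0.14, 0.60) and DNA replication genes (median 0.01, mean -0.05, 0.67). Lists with 1 tested member have values only, given for the pairs numbered 1 and 2, and none was called. GI changed by -1.27 and -0.96, TRY by -0.82 and -1.11, and AN by -0.12 and -0.33. PDF1.2 changed by -0.10 and 3.28, and EXPA18 by 0.06 and 0.13.

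Few genes rose at both ages. AT4G03610, AT3G01015 and 264823_at were called higher at 5 d and at 15 d, 3 where independent calls would share 0.13 (Fisher's exact test, p = 2.8e-04), and no fall was shared (p = 1 by the same exact test). Both comparisons share 1 spread estimate per probe set, so their calls are not independent, as the exact test assumes. Without the floor only 1 rise was shared (Fisher's exact test, p = 0.079). AT4G03610 had 15 d signals of 9.25 in wild type and 281 in the mutant. Across all probe sets, which are not independent replicates, the mutant effects at the 2 ages had a correlation of -0.08.

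A test of the difference asked whether the mutant effect changed with leaf age. Where 15 d wild type was at the floor, the difference is at least the value given. The effect was larger at 15 d than at 5 d for the G2/M genes AUR2, by at least 4.11 on the log2 scale (SE 0.29, adjusted p = 0.0014), KINESIN-12B, by 2.93 (SE 0.34, adjusted p = 0.012), and 3xHMG-box1, by at least 4.21 (SE 0.68, adjusted p = 0.048). For AT4G01730, which is on none of the lists, it was larger by at least 4.73 (SE 0.32, adjusted p = 0.0014). AT3G10310 (at least 3.52), AT1G23790 (at least 3.51), AT5G48310 (at least 3.49), AT4G15830 (3.46, with 1 of 3 wild-type arrays at the floor), the kinesin gene AT1G72250 (at least 3.46) and the chromosome segregation gene AT5G15510 (at least 2.43) followed with adjusted p = 0.0048 to 0.018. It was smaller at 15 d for AT1G65490 (-3.88, adjusted p = 0.0048), MSRB5 (-3.70, adjusted p = 0.022) and AT3G56290 (-2.71, adjusted p = 0.017). AT1G13650 (adjusted p = 0.0026) and EXPB1 (adjusted p = 0.047) were called lower too, but nearly all their 15 d arrays were at the floor, which gives no size for that age. In all, 41 effects were higher and 16 lower at 15 d (57 calls by limma, 1208 at an unadjusted p under 0.05). The G2/M list differed by a median of 2.51 (adjusted p = 1.8e-11, and 0.018 with an estimated correlation), with 3 of 8 genes called and 6 over the list alone. Kinesin genes (4 of 28 called, 7 over the list alone; median 0.29, mean 0.74, adjusted p = 9.8e-07) and chromosome segregation genes (1 of 12, 4 over the list alone; 0.65, 3.3e-06) had a higher effect, with adjusted p = 0.20 and 0.064 with an estimated correlation. Nuclear photosynthesis genes (median -2.12, adjusted p = 9.8e-07) and glutathione S-transferase genes (-1.03, 0.0024) had a lower effect with no called member, with adjusted p = 0.23 and 0.064 with an estimated correlation. Over the list alone 1 photosynthesis gene was lower, and 4 transferase genes were lower and 1 higher. Tubulin genes had a higher effect (median 0.49, adjusted p = 0.032; adjusted p = 0.20 with an estimated correlation).

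The tubulin result was lost under quantile normalization (adjusted p = 0.060) and without 5 d wild-type replicate 2 (0.16), 5 d mutant replicate 1 (0.055) or 2 (0.051) or 15 d mutant replicate 1 (0.24). The lists not called in this test were DNA replication (adjusted p = 0.76), core histone (0.93; median -0.04, mean 0.06, up by the test), ribosomal (0.68; 0.00083 without 15 d mutant replicate 1), expansin and XTH (0.68, with EXPB1 lower), UDP-glycosyltransferase (0.16; 0.046 under the stricter filter, 0.041 without 15 d wild-type replicate 1), plastid-encoded (0.68; 0.0098 without 5 d wild-type replicate 2) and mitochondrion-encoded genes (0.48; 0.020 without 5 d mutant replicate 2). AT4G01730, AUR2, AT3G10310 and AT1G13650 were called without each array. AT1G23790 (adjusted p = 0.067), AT5G48310 (0.058) and AT1G65490 (0.056) were not called without 5 d mutant replicate 2, nor KINESIN-12B without either 5 d replicate 2 (0.076 and 0.083). The other named genes lost their call without several arrays each (adjusted p = 0.053 to 0.27): 3xHMG-box1 without any 15 d wild-type, any 5 d mutant or 15 d mutant array 2 or 3; AT1G72250 and AT4G15830 without either 5 d wild-type array, 15 d wild-type array 2 or 3, 5 d mutant array 2 or 15 d mutant array 3. For MSRB5, EXPB1, AT5G15510 and AT3G56290 these were the 5 d arrays numbered 2, 15 d wild-type arrays 2 and 3, and 15 d mutant array 2. MSRB5, EXPB1 and AT5G15510 also lost it without 15 d mutant array 3, and MSRB5 and EXPB1 without 15 d wild-type array 1. The count was 91, 22, 39, 21 and 24 without 5 d wild-type replicate 1 and 2 and 15 d wild-type replicate 1, 2 and 3. It was 447, 8, 564, 26 and 26 without 5 d mutant replicate 1 and 2 and 15 d mutant replicate 1, 2 and 3. Most of these effects were lower without 5 d mutant replicate 1 (84 higher, 363 lower) or 15 d mutant replicate 1 (199 higher, 365 lower). With the pairing it was 181 (75 higher, 106 lower).

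From 5 d to 15 d, lists of cell division and ribosomal protein genes fell in wild-type leaves. Where a group was partly or wholly at the floor, the changes with age given here and for the triple mutant are at least the values printed. All 8 tested G2/M genes fell, by a median of 4.36 on the log2 scale (camera adjusted p = 2.7e-06; adjusted p = 0.070 with an estimated correlation); AUR2 fell by 5.81 (SE 0.21, adjusted p = 1.4e-06) and 3xHMG-box2 by 6.10 (SE 0.52, adjusted p = 2.7e-05). All 45 ribosomal protein genes fell (median -2.29), as did 20 of 28 kinesin genes, 11 of 12 chromosome segregation genes (BUB3.1 by 3.62), 7 of 7 DNA replication genes and 7 of 8 core histone genes (HTB1 by 2.99); 1 kinesin gene rose. Camera called each of these lists lower (adjusted p = 1.0e-13, 1.8e-07, 6.5e-07, 0.0013 and 0.0071), with adjusted p = 0.21, 0.18, 0.070, 0.18 and 0.21 with an estimated correlation. SPCH and MUTE, regulators of stomatal precursor cells, fell by 4.07 and 1.46, PRL of the replication helicase by 3.54, ICU2, a DNA polymerase gene, by 1.29, and TRY by 2.03. The 4 senescence genes, too few for a list test, rose by a median of 3.31, WRKY53 at least 21.1-fold (4.40, adjusted p = 2.9e-05), and GI rose by 1.99. Of the cell wall genes 5 expansin or XTH genes rose, XTH19 at least 82.8-fold, and 5 fell, XTH16 by 4.29. UDP-glycosyltransferase genes were higher (15 up, 3 down of 36; median 0.86, adjusted p = 0.0013; adjusted p = 0.19 with an estimated correlation), UGT72E1 by 5.28 and UGT84A3 by 4.69. Glutathione S-transferase genes were higher too (5 up, 1 down of 8; 1.95, 0.031; adjusted p = 0.18 with an estimated correlation), GSTL3 by 3.71. The list missed the threshold with a replicate block across ages (adjusted p = 0.051).

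The largest named changes in wild type were rises of AT2G25510 (9.13, SE 1.23, adjusted p = 2.9e-04; 44.6 ± 6.49, n = 2, against 24913 ± 901, n = 3), of the formate dehydrogenase gene FDH (8.20) and of the chitinase gene ChiC (at least 265-fold), and falls of AT4G29030 (at least 268-fold), AT1G73620 (-7.13) and ATLP-1 (-6.40). Limma called 4130 probe sets higher and 4521 lower at 15 d in wild type (9604 at an unadjusted p under 0.05). Quantile normalization moved the median change of all probe sets from -0.01 to -0.14 in wild type and from -0.05 to -0.12 in the triple mutant. Mitochondrion-encoded genes were higher (4 of 12 called, median 1.28, adjusted p = 0.047; adjusted p = 0.51 with an estimated correlation). They missed the threshold without 5 d wild-type replicate 1 (adjusted p = 0.14), 15 d wild-type replicate 1 (0.057) or 3 (0.079) or 15 d mutant replicate 1 (0.068), and with a replicate block across ages (0.063). Photosynthesis (adjusted p = 0.25; LHCB4.3 and AT1G56190 up), tubulin (0.14; TUB7 and TUA6 down), expansin and XTH (0.97; median 0.03, mean 0.44, down by the test) and plastid-encoded genes (0.97; median -0.36, up by the test; 3 up) were not called as lists.

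In the triple mutant the leaves changed with age in much the same genes: 4283 probe sets were higher and 4483 lower at 15 d (9742 at an unadjusted p under 0.05), and 3447 rises and 3697 falls were shared with wild type, against 4 and 1 that went opposite ways. The mutant and wild-type changes were tested against each other only by the difference above. G2/M genes fell (6 of 8 called, median -1.89, adjusted p = 0.0028; adjusted p = 0.23 with an estimated correlation), including 3xHMG-box2 (-4.22) and AT1G63100 (-4.33). Ribosomal protein genes fell in 45 of 45 (median -2.17, adjusted p = 6.4e-14), kinesin genes in 15 of 28 with 1 rise (-1.40, 2.7e-05), chromosome segregation genes in 11 of 12 (-1.88, 2.1e-05), replication genes in 7 of 7 (-2.04, 0.0017) and core histone genes in 6 of 8 (-2.11, 0.010). UDP-glycosyltransferase genes were higher (18 up, 5 down of 36; 1.12, 0.0097), all 6 lists with adjusted p = 0.23 with an estimated correlation. HTR12, the centromeric histone gene, fell by 3.09, and TUB7 (-1.86), PRL (adjusted p = 7.9e-06) and SPCH (-4.02) fell too. XTH19 rose by 5.45, UGT72E1 by 4.40, WRKY53 by 3.98, GI by 2.98, GSTL3 by 2.76, COR47 by 2.49 and the sugar transporter gene SWEET11 by 5.82. Senescence genes rose in 4 of 4 (median 3.89). Mitochondrion-encoded genes were higher (7 of 12 called, median 1.60, adjusted p = 0.014; adjusted p = 0.44 with an estimated correlation), but not without 5 d mutant replicate 1 (adjusted p = 0.054). Photosynthesis genes (adjusted p = 0.12; 9.9e-04 without 15 d mutant replicate 1), glutathione S-transferase (0.098), tubulin (0.41), expansin and XTH (0.77) and plastid-encoded genes (0.77) were not called.

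Genes that rose in the 15 d triple mutant were often genes that wild-type leaves lose with age: 75 of the 120 (62.5%) were lower at 15 d than at 5 d in wild type, against 27.3% of all tested, and 11 were higher. Independent lists would share 32.8. The comparisons share the 15 d wild-type arrays, and simulated data without mutant effects gave a share of 38.7% on average and 46.7% at most over 20 draws. When the 3 shared arrays were split 1 against 2 between the comparisons, a test chosen after seeing the data, 63.5 to 86.5% of the 34 to 104 rises were lower with age over the 6 ways to split them. Of all probe sets tested, 17.57 to 27.4% were. In the mutant 40 of the 120 were lower with age, against 4483 of all 16558 tested. The 120 were picked for high signal in the same 15 d mutant arrays, so a count below the 75 of wild type is partly built in.

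In single seedling arrays, the G2/M genes were higher in the triple mutant and highest in the quadruple mutant. Their median log2 ratio over wild type for the 8 genes was 0.85 in the myb3r1 myb3r3 myb3r5 and 1.25 in the quadruple mutant, both at the 100th percentile of random lists. It was 0.41 in myb3r4 (percentile 99.8) and in myb3r3 myb3r5 (99.9), 0.23 in myb3r1 (98.2), 0.20 in myb3r1 myb3r4 (96.8), 0.13 in myb3r5 (83.7), 0.08 in myb3r3 myb3r4 myb3r5 (81.8) and -0.06 in myb3r3 (26.8). The probe sets that rose in 15 d triple mutant leaves, 119 of which were measured in seedlings, had medians of 0.91 in the myb3r1 myb3r3 myb3r5 mutant, 0.94 in the quadruple, 0.63 in myb3r3 myb3r5, 0.44 in myb3r3 myb3r4 myb3r5 and 0.32 in myb3r3, each at the 100th percentile. In myb3r1, myb3r4, myb3r5 and myb3r1 myb3r4 they were 0.12, 0.07, 0.13 and 0.13 (percentiles 99.92, 74.9, 99.84 and 99.99), and 111 of 119 were above 0 in the triple mutant against 68 in myb3r4. The 4 probe sets that fell in 15 d leaves had medians of -0.70 in myb3r1 myb3r3 myb3r5, -0.55 in myb3r3 myb3r4 myb3r5 and -0.42 in the quadruple mutant, and of -0.36 to 0.01 in the other 6 genotypes. The 3 that fell in 5 d leaves mostly went the other way, with 0.47 in myb3r3 myb3r4 myb3r5, 0.45 in myb3r4, 0.41 in myb3r3, 0.22 in myb3r3 myb3r5, 0.19 in myb3r5, 0.17 in the quadruple, 0.05 in myb3r1, -0.01 in myb3r1 myb3r3 myb3r5 and -0.29 in myb3r1 myb3r4. The 18 rises of 5 d leaves had a median of 0.32 in myb3r3 myb3r5 (100th percentile), 0.22 in the quadruple (99.7), 0.20 in myb3r1 myb3r3 myb3r5 (97.3) and 0.00 in myb3r3 myb3r4 myb3r5 (39.45). Their median was 0.13 in myb3r1 myb3r4 (96.3), 0.10 in myb3r1 (82.5) and in myb3r5 (88.1), -0.03 in myb3r4 (30.9) and -0.04 in myb3r3 (15.8). The 9 ratios share 1 wild-type array, so they are not independent of each other, and none has a replicate check. The percentiles are not p-values, since genes that vary together can reach an extreme one at a small median. The 47 cytosolic ribosomal protein genes stood at percentiles of 99.5 to 100 in myb3r4, myb3r5, myb3r1 myb3r4 and myb3r3 myb3r4 myb3r5. Their medians there were 0.10 to 0.14. In the other genotypes they stood at percentiles of 66.9 to 97.3.

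**Figure D4:**
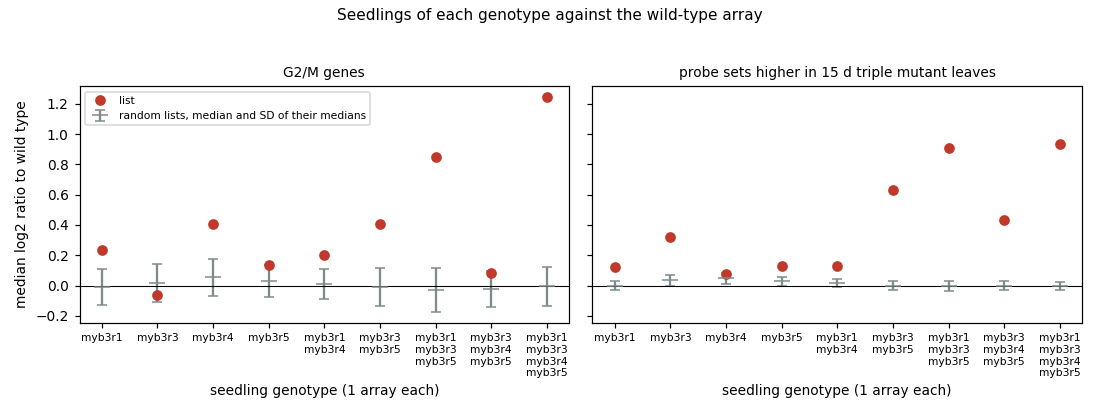
Median log2 ratio over wild type in each mutant seedling array, for the 8 G2/M genes and for the 119 probe sets that were higher in 15 d triple mutant leaves; grey marks the median and SD of random lists. The G2/M median was 0.85 in the myb3r1 myb3r3 myb3r5 and 1.25 in the quadruple mutant.

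Among single genes in seedlings, the unnamed probe set 264823_at, which also rose in leaves of both ages, was 34.6-fold higher in the myb3r1 myb3r3 myb3r5 mutant (signal 1785 against 51.6 in wild type) and 259007_at 19.6-fold. The defensin gene PDF1.2b was 6.92-fold higher there and 6.59-fold higher in myb3r1 myb3r4, and PDF1.2 was 16.5-fold higher in the quadruple mutant (12724 against 773). AT3G60070 (-2.22), AT3G22060 (-2.21) and AT3G59780 (-2.10) were lower in the myb3r1 myb3r3 myb3r5 mutant. AT3G02120 was lower in myb3r1 myb3r4 (50.5 against 407) and in the quadruple mutant (39.7), where AT2G42110 was at least 8.39-fold and AT4G19430 8.02-fold lower; AT3G55710 was lower in myb3r1 myb3r4 (-2.49).

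The additive fit asked how expression changed with each mutant allele across the 10 seedling arrays. AT5G55180 was lower with the myb3r4 mutation, at 761 ± 221 (SD, n = 4) against 2139 ± 282 (SD, n = 6) without it (term -1.45, SE 0.12, limma adjusted p = 0.014), and AT1G31335 was lower, at 240.0 ± 64.7 against 648 ± 79.5 (-1.46, SE 0.12, adjusted p = 0.014). These and 252078_at (-2.32, adjusted p = 0.0014) were its 3 calls, all lower (1106 at an unadjusted p under 0.05). The myb3r3 term had 1 call, 259007_at, at 6720 ± 5229 (SD, n = 5) against 174 ± 29.4 (SD, n = 5) (term 5.52, SE 0.44, limma adjusted p = 0.027), with 2049 at an unadjusted p under 0.05. The myb3r3 count was 0 with no filter, no variance trend or a myb3r1 by myb3r4 interaction. It was far higher without the floor, with a pseudocount or with the stricter filter. Limma called none for myb3r1 (1948 unadjusted) or myb3r5 (1508 unadjusted). The myb3r3 and myb3r5 alleles occur together in every array that carries either, except the myb3r3 and myb3r5 single mutants. Their terms are thus told apart only through those single arrays. The simulated recovery was measured for the myb3r4 term only. The counts ran from 0 to 23 for myb3r3 and for myb3r5 as single arrays were left out, with 23 without the myb3r5 array in both; for myb3r4 the count was 0 without that array. The median terms of the 8 G2/M genes were 0.30 for myb3r1, 0.22 for myb3r3, 0.10 for myb3r4 and 0.19 for myb3r5. None was called over all probe sets, and 1, 0, 1 and 0 were called when adjusted over the list alone. With myb3r3 and myb3r5 as 1 term, 17 probe sets were called, all higher (2144 unadjusted), among them AT1G03920 (1.26, adjusted p = 0.021) and AT5G42370 (0.61, adjusted p = 0.018), chosen after their values were seen; 5 of 8 G2/M genes were then called over the list alone. The myb3r1 by myb3r4 interaction had no call (970 unadjusted).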

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

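The tests of tissue age, of scaling, of RNA quality and of senescence were chosen only after the results were seen; the test of other splits of the samples was chosen before. The results below were picked out because the mutant effect differed between 5 d and 15 d leaves in the test of that difference: 57 probe sets, and the genes and lists given here. The effect was higher at 15 d for AT4G01730 (4.73), 3xHMG-box1 (4.21), AUR2 (4.11), AT3G10310 (3.52), AT1G23790 (3.51), AT5G48310 (3.49), AT4G15830 (3.46), AT1G72250 (3.46), KINESIN-12B (2.93) and AT5G15510 (2.43), in log2 units. It was lower at 15 d for AT1G65490 (-3.88), MSRB5 (-3.70), AT3G56290 (-2.71), AT1G13650 (-2.67) and EXPB1 (-1.36). Floored groups make the higher values lower limits where 15 d wild type was at the floor, and give AT1G13650 and EXPB1 no size at 15 d. By list, the median differences were 2.51 for G2/M genes, 0.29 for kinesin, 0.65 for chromosome segregation, -2.12 for nuclear photosynthesis, -1.03 for glutathione S-transferase and 0.49 for tubulin genes.

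In the 15 d triple mutant the G2/M genes rose by a median of 2.76. Younger tissue in the mutant samples, taken as an admixture of 5 d type RNA, would need a share of 46.3% (median over the 5 called genes, 27.6 to 58.4%). That share predicts a median change of 1.47 in the 45 ribosomal protein genes. They changed by -0.043 (SD 0.182), which argues against such an admixture. The share was read only from genes that rose. Leaves aged between 5 d and 15 d were not measured, so tissue of intermediate age was not tested. The scaling of the arrays is argued against too, since the median was 2.77 under quantile normalization. The 6 samples make only 10 splits into groups of 3, too few for a share under 0.05; the real split called 124 probe sets and the highest other 920, 2 of 10 with as many calls. That split put wild-type replicates 1 and 2 with mutant replicate 1 and points to a structure of the samples apart from genotype. The other 3 splits that part all 3 numbered pairs called 0. These counts cover all probe sets. The G2/M list itself followed genotype, with mean log2 signals of 7.57, 7.43 and 7.40 in mutant replicates 1, 2 and 3. In wild type they were 5.61, 5.06 and 5.24. For this list the values argue against that structure. An effect of the mutations on these genes stays open as a hypothesis.

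Nuclear photosynthesis genes were lower in the 15 d triple mutant by a median of 1.42 on the log2 scale. The scaling of the arrays is argued against: under quantile normalization the median was -1.51 (SD of members 0.603). RNA quality stays open: the control GAPDH 3′ over 5′ ratio was 1.27 ± 0.334 in the mutant and 1.34 ± 0.448 in wild type (SD, n = 3 each), within the spread of either group. The actin ratio was 17.5 ± 6.21 and 15.1 ± 6.40, higher in the mutant in 3 of 3 numbered pairs, and the ubiquitin ratio 2.29 ± 0.0603 and 2.34 ± 0.0815, higher in 1 of 3. A stress or senescence state of the mutant samples may also contribute, since the 4 senescence genes had a median change of 0.625 (SD 0.383), none of them called; with so few genes this cannot be told apart from the genotype. The structure of the samples apart from genotype stays open too. The list's mean log2 signal at 15 d was 13.39, 12.79 and 13.02 in wild-type replicates 1 and 2 and mutant replicate 1. It was 12.40, 10.42 and 10.84 in wild-type replicate 3 and mutant replicates 2 and 3, the other side of the split with 920 calls. In each numbered pair the list was lower in the mutant. The mutations themselves stay among the open explanations, untested.

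Of the 18 rises in 5 d triple mutant leaves, 9 (50%) were genes that rise with leaf age. Simulated data without mutant effects gave 58.9% through the shared 5 d wild-type arrays. With no array shared it was 6 of 11 (54.5%) or 0 of 1, against 18.9% of all tested, so the overlap alone does not settle whether the tissue was older. Over 1104 other strongly age-rising probe sets, the older tissue test gave a median of 1.15 (SD 1.04) in mutant replicate 2, which is consistent with older tissue or a mixed sample there. In replicate 1 it was 0 (SD 0.593), the value that probe sets at the floor give. The share to compare it with is read from genes picked with those shared arrays. Older tissue therefore cannot be told apart from the genotype there.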

How the results depend on the processing

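The replicate block within each age, the leave-outs of both 15 d arrays of one number and the splits of the wild-type arrays of one age between comparisons were chosen after seeing the data; the other alternatives were chosen before. Of the counts and seedling values under all alternatives, 212 were within 1.5 times the main count or within the spread. Another 28 rose past that, 40 fell under it and 14 moved. Of list tests 1165 kept direction and side of the threshold, 23 became calls, 57 lost the call and 3 turned. Of named genes 5483 kept both, 27 became calls, 261 lost the call and 0 turned. These tallies include the values as deposited, whose arrays already had nearly the same trimmed mean. That setting could hardly differ from the main fit, and all 277 named genes stayed the same under it. Signal over background limits genes at the floor, whose folds are bounds, and group sizes limit the rest. Arrays set to the floor have equal values, so the spread and adjusted p of such genes depend on the floor too. For the values below the cause was not tested, except that fewer arrays or fewer degrees of freedom enter the leave-outs, the blocks and the fits of single comparisons.

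Calls at 5 d (21) became 34 under quantile normalization, 10 with a pseudocount, 75 with no filter, 72 with an ordinary linear model, 6 with a replicate block across ages, 52 with the block within each age and 1 with only the groups of the comparison; leaving out arrays gave 4 to 523. Calls at 15 d (124) became 779 with the block within each age and 67 with only the groups of the comparison, and leave-outs gave 43 to 1552. Calls for the difference (57) became 87 with no filter, 34 with the replicate block across ages and 181 with the block within each age; leave-outs gave 8 to 564. The block within each age changed no call of a comparison, list or named gene other than those given in the report. Leaving out 1 of the 5 d arrays leaves a group with a lone sample, which is assumed to vary like the other groups. Without the floor 95 probe sets were called at 15 d, and 86 of them were among the 124. At 5 d 17 were called, 12 of them among the 21. For the difference 39 were called, 33 of them among the 57. The other calls of the main fit were lost without the floor.

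With an estimated correlation the fall of the G2/M genes with age had adjusted p = 0.0704 in wild type and 0.229 in the triple mutant. The overlap of rises at both ages was 1 without the floor (Fisher's exact test, p = 0.079) and 5 with no filter (p = 1.1e-06), against 3. For ribosomal protein genes at 15 d, turned up without mutant replicate 1 (adjusted p = 0.0013) and without both arrays numbered 1 (0.015), the leave-outs ran from 0.00053 to 0.757; for plastid-encoded genes, turned down without both numbered 3 (0.042), they ran from 0.00115 to 0.942.

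Medians of the 15 d leaf rises in seedlings moved as follows. Without the floor they were 0.36 in myb3r3, 0.25 in myb3r4, 0.66 in myb3r3 myb3r5, 1.05 in myb3r1 myb3r3 myb3r5 and 1.12 in the quadruple mutant. Under quantile normalization they were 0.090 in myb3r5, 0.073 in myb3r1 myb3r4, 0.94 in myb3r1 myb3r3 myb3r5 and 0.98 in the quadruple. With a pseudocount they were 0.10 in myb3r5, 0.11 in myb3r1 myb3r4, 0.53 in myb3r3 myb3r5, 0.83 in myb3r1 myb3r3 myb3r5 and 0.88 in the quadruple.

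For the allele terms, the myb3r1 count was 3 with a pseudocount and 2 with the stricter filter. The myb3r3 count was 42 without the floor, 49 with a pseudocount, 46 with the stricter filter, and 0 with no filter, with no variance trend and with the myb3r1 by myb3r4 interaction; leave-one-out gave 0 to 23. The myb3r4 count was 13 without the floor, 14 with a pseudocount, 12 with the stricter filter, 1 with no filter, 0 with the interaction and 5 with myb3r3 and myb3r5 as 1 term; leave-one-out gave 0 to 4, and 0 to 23 for myb3r5. The planned search for promoter motifs was not run.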

Other observations

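The test near the mutated loci was chosen only after the results were seen; the permutations of the allele terms were chosen before. In single seedling arrays, plastid-encoded genes were lower in several genotypes. The median log2 ratio of the 47 genes was -0.35 in the myb3r1 myb3r3 myb3r5 mutant, -0.34 in the quadruple and -0.20 in myb3r3 myb3r4 myb3r5, each at percentile 0 of random lists, -0.14 in myb3r3 myb3r5 (percentile 0.07) and -0.08 in myb3r1 (percentile 0.75). It was 0.29 in myb3r4 (100th percentile). The median allele terms were -0.18 for myb3r1, -0.14 for myb3r3, 0.11 for myb3r4 and -0.14 for myb3r5, with no gene called over all probe sets. Between leaf replicates of one group the list's mean log2 signal differed by far more, with 9.21 and 10.81 in 5 d wild type. In the 15 d triple mutant it was 10.51, 8.56 and 10.73. Seedlings have no replicates from which such a spread could be read. Nuclear photosynthesis genes (11) had their lowest medians in myb3r5 (-0.20, percentile 0.315) and myb3r4 (-0.18, percentile 3.19), with -0.16 in the quadruple (6.75; 1 of 11 above 0), 0.00 in myb3r1 myb3r3 myb3r5 (26.3) and 0.18 in myb3r3 (98.0).

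Kinesin genes had their highest seedling median in myb3r4 (0.31 over 31 genes, percentile 99.95; 27 above 0), with 0.18 in myb3r1 myb3r4, 0.15 in the quadruple and 0 in the myb3r1 myb3r3 myb3r5 mutant. Chromosome segregation genes had medians of 0.32 in myb3r4, 0.29 in myb3r3 and in myb3r1 myb3r3 myb3r5, and -0.15 in myb3r3 myb3r4 myb3r5 (percentile 8.92; 3 of 12 above 0). Tubulin genes had a median of 0.32 in myb3r3 (7 genes, percentile 99.9), and mitochondrion-encoded genes of 0.42 in myb3r4 (14 genes, percentile 99.95; 8 above 0) but -0.18 in the quadruple (percentile 2.42; 3 above 0). Expansin and XTH genes had 0.37 in myb3r3 (percentile 99.98; 20 of 25 above 0), 0.24 in myb3r1 myb3r3 myb3r5 and 0.19 in myb3r1 myb3r4 (25 genes, percentiles 99.7 and 99.5). These are values of single arrays over the same wild-type array, and the limit of the percentiles given above holds here too.

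The mutant alleles of the 10 seedling arrays were assigned in 100 ways, the real one among them. For myb3r4 (3 calls) 1 of 100 assignments, the real one, gave as many calls, the highest other being 2, and for myb3r3 (1 call) 2 of 100 did, the highest other being 1, shares of 0.04 when adjusted over the 4 terms. These shares lie under 0.05 in this fit, but counts this small among 100 assignments do not exclude chance. The myb3r3 call, 259007_at, had signals of at least 2873 in arrays with that mutation and at most 198 in those without. Limma also called it higher in 15 d triple mutant leaves (log2 change 3.33, adjusted p = 1.8e-04), but not at 5 d. For this probe set the values argue against chance. The leaf mutant also carries myb3r1 and myb3r5, so the leaf values do not single out myb3r3. The myb3r3 count was 0 with no filter, no variance trend or the interaction. The myb3r4 count was 0 with the interaction, and those fits were not permuted. For myb3r1 and myb3r5, with 0 calls, the test could not come out otherwise (100 of 100, highest others 9 and 1) and says nothing about chance. Low p-values were 1.60 times as frequent near the mutated loci as elsewhere (Fisher's exact test, p = 0.248), so linked strain or insertion effects cannot be told apart from chance at this number of genes.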
